A study of Gadus morhua with 47 samples.

How the data were processed

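Precision-cut liver slices of Atlantic cod (Gadus morhua), thin sections of liver kept alive in culture, were exposed to the vehicle dimethyl sulfoxide (DMSO), to benzo[a]pyrene (BaP), to ethynylestradiol (EE2), or to a mixture of both (Mix) in which each compound was at the stated dose. Each compound was used at 10 nM and at 1 µM. BaP is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor, and EE2 is a synthetic estrogen. Per the labels' protocols, total RNA was treated with DNase, and libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument as paired reads. The 47 libraries came from 8 fish, 5 males and 3 females, and the replicate number in a library's name is the number of the fish.

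The deposited count tables were made by the authors with FastQC 0.11.5, HISAT2 2.1.0 and SAMtools 1.4.1, per the submitters' processing notes. The genome or transcript build and the options of the aligner are not given in the sources used here. Each deposited table gives, for 22100 transcripts, an Ensembl cod transcript identifier, a length, the count of mapped read segments and the count of unmapped segments whose mate was mapped. The values are whole counts that were not normalized. Both mates of a pair are counted, so 1 sequenced fragment can add 2 to a transcript. Counts may also include secondary alignments, so transcripts of near-identical genes could have shared reads, and a change named for 1 transcript is uncertain in that respect. Lengths were multiples of 3 for 99.99% of the transcripts, and they are called coding lengths here. The last row of each table held segments placed on no transcript and stayed out of library sizes and tests. The segments of that row made up 41.8% to 57.8% of all segments in a library. Unmapped segments whose mate was mapped made up a further 9.1% to 11.7%, and mapped segments 33% to 47%.

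The deposited files do not pair transcript identifiers with gene names. The name table given for this species, made for assembly gadMor3.0 with 33114 genes, matched 0 of the identifiers. Gene names are therefore not used, and the pathway and cell type lists fixed before the data were examined could not be applied. The design fixed beforehand then allowed at most 2 identifiers that rose and 2 that fell, taken from transcripts with an adjusted p under 0.05, an average log2 CPM of 0 or more and the same direction in all but at most 1 of the fish that had both slices. Which identifiers to print was chosen after the results were seen. The rises are the largest with BaP 1 µM and with EE2 10 nM, and the falls are the largest with EE2 10 nM and with Mix 1 µM against DMSO.

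Mapped counts per library ranged from 36.6 M to 67 M segments (M, mega), with a median of 49.1 M. A limit of 3 counts corresponded to 0.0448 to 0.0820 CPM (counts scaled to a common library total) before TMM scaling, depending on the library. Intervals on ratios of counts are exact 95% binomial intervals on counts pooled over the slices of a group. They cover counting error only and leave out the variation between fish and the pairing of slices. Reads carried no molecular identifiers. Since both mates of a fragment are counted, the counts are not independent, and these intervals are too narrow even for counting error.

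Differential expression was tested on the counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the default expression filter by treatment group (minimum count 10, minimum total count 15), which kept 17824 transcripts. One fit held all 47 libraries with treatment and fish as terms, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are given with their standard errors (SE). Interactions between BaP and EE2 were contrasts of the same fit, and interactions between sex and treatment were terms of a second fit. Female and male DMSO slices were compared without a block, over 16813 transcripts. Log2 CPM for levels per library used a prior count of 2.

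Fish was kept as a block because every replicate number carried the same sex, body weight and liver weight in all groups. Libraries of the same fish deviated together from the group means, with a mean correlation of 0.694 across transcripts against -0.0934 for different fish. The lowest correlation within a fish was -0.354, and without the 4 libraries described below it was 0.417. No 2 libraries had identical counts.

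Because the lists could not be applied, 2 transcript sets were defined after the data were seen. The EE2 set holds the 41 transcripts that rose in Mix 10 nM against BaP 10 nM. The BaP set holds the 6 transcripts that rose in Mix 1 µM against EE2 1 µM. Each set was then read only in comparisons that did not repeat the contrast that defined it, as the median log2 fold change of its members, as the mean change per fish with an exact two-sided sign-flip test, and with the rotation test fry of limma 3.58.1. None of the 14 readings compared a group of the contrast that defined the set. All comparisons drew on the same fish, and the medians and fry on models of all libraries. The readings are therefore not fully independent of that contrast. Benjamini-Hochberg values cover the 14 readings. Placing members with 0 counts in the reference group at their bound of 3 counts left the medians as given, except for the EE2 set with BaP 1 µM, where it was -0.09 in place of -0.08.

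Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, RLE factors, no filter on low counts, a stricter filter (CPM of 1 in at least 24 libraries), no fish block, fish as a random effect (limma with statmod 1.5.0), fits of only the groups compared, male fish only, and leaving out each fish in turn. Alternatives chosen after seeing the data left out 4 libraries with a TMM factor under 0.8, also with RLE factors or with each library's length slope as a covariate, or left out fish 7 and 8. The tests were tried on simulated counts for EE2 1 µM against DMSO with 200 of 17645 transcripts changed. The counts were drawn independently from means fitted with fish as the only term, which favors a fish block. They left out the deviations that the 4 libraries shared, so the rates may not hold for these data. The edgeR fit with the fish block recovered 67% of the transcripts changed 2-fold and 92% of those changed 4-fold, with 8 false calls among 167. Without the block it recovered 19% and 72%. DESeq2 recovered 74% and 93% with 29 false calls among 196 and 1 call in a group without changes, and limma recovered 62% and 88% with 6 false calls among 156. Figures were drawn with matplotlib 3.10.9.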

Results

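The transcriptome of cod liver slices was measured in 8 DMSO slices, 7 slices each with BaP 10 nM, BaP 1 µM and EE2 10 nM, and 6 slices each with EE2 1 µM, Mix 10 nM and Mix 1 µM. The question set by the design was how each compound, its dose and the presence of the other compound changed transcript levels in liver tissue. Slices of each fish were spread over the treatments, and no fish lacked a DMSO slice. In units of M (mega), libraries held 36.6 to 58.6 M mapped segments with DMSO, 41.9 to 63.5 with BaP 10 nM, 44 to 67 with BaP 1 µM, 43.7 to 53.1 with EE2 10 nM, 45.3 to 63.3 with EE2 1 µM, 41.8 to 59.8 with Mix 10 nM and 39 to 54.5 with Mix 1 µM. Between 15975 and 19355 transcripts were detected per library, and the 10 most abundant took 15.3% to 22.9% of the counts. The first principal component carried 26.1% of the variance, and 83.7% of its spread lay between fish and 2.54% between treatments.

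Of the 47 libraries, 4 stood apart from the other slices of their fish. They were DMSO of fish 2, BaP 10 nM of fish 6, BaP 1 µM of fish 7 and Mix 1 µM of fish 8, with TMM factors of 0.678, 0.587, 0.758 and 0.572 against 0.832 or more in all others. They lay in 4 different treatment groups, and counts without them are given where they differed most.

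With BaP 1 µM, 12 of 17824 transcripts rose against DMSO and 0 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The median rise was 1.71 on the log2 scale, and 4 transcripts rose at least 8-fold. The largest change was that of ENSGMOT00000000331.1, with a coding length of 1560 bases, whose level went from 27 CPM ± 22.9 (SD, n = 8) with DMSO to 1430 CPM ± 708 (SD, n = 7). Its log2 fold change was 6.35 ± 0.56 (SE), with an edgeR adjusted p of 6.11e-10, and it was higher in 7 of 7 fish. The transcript with the next largest change had a log2 fold change of 5.5 ± 0.70 (SE) and was also higher in 7 of 7 fish. With fish as a random effect in limma that transcript did not pass, at a log2 fold change of 5.06 and an adjusted p of 0.139. All 6 members of the BaP set rose, with a median log2 fold change of 4.48, and the mean change per fish was 4.11 ± 0.91 (SD, n = 7). The count was 6 without the fish block, 7 without fish 4 and 3 in the fit of only these groups. It was 31 with DESeq2 and 23 without the 4 libraries, of which 17 rose and 6 fell.

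With BaP 10 nM, 0 transcripts passed the edgeR test against DMSO, 281 had an unadjusted p under 0.05, and DESeq2 and limma also called 0. The 281 are fewer than the share of 0.05 of the 17824 transcripts that chance alone would give. Such counts below are also under that share, except for the interaction of sex with Mix 1 µM. So is the count of 696 for EE2 10 nM against DMSO, where 51 transcripts passed. Counts under that share can arise from p-values that are too large, which was not tested. They do not make 0 calls stronger evidence that transcripts were unchanged. ENSGMOT00000000331.1 stood at 64.9 CPM ± 41.4 (SD, n = 7), and its log2 fold change was 1.21 ± 0.45 (SE) with an edgeR adjusted p of 1. As a group, the 6 transcripts of the BaP set were higher, with a median log2 fold change of 0.97 and a fry p adjusted over 14 readings of 0.0122. Their mean change per fish was 0.89 ± 0.82 (SD, n = 7), higher in 6 of 7 fish, with an exact sign-flip p of 0.0312 and an adjusted exact value of 0.0546. Without the 4 libraries 1 transcript was called.

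The dose comparison for BaP gave 6 rises and 0 falls in BaP 1 µM against BaP 10 nM. All 6 were among the 12 that rose with BaP 1 µM against DMSO. ENSGMOT00000000331.1 was higher at the higher dose by 5.14 ± 0.56 (SE) on the log2 scale, with an edgeR adjusted p of 4.65e-07, in 6 of 6 fish. The BaP set differed between the doses by a mean of 3.24 ± 0.52 (SD, n = 6) per fish.

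**Figure D1:**
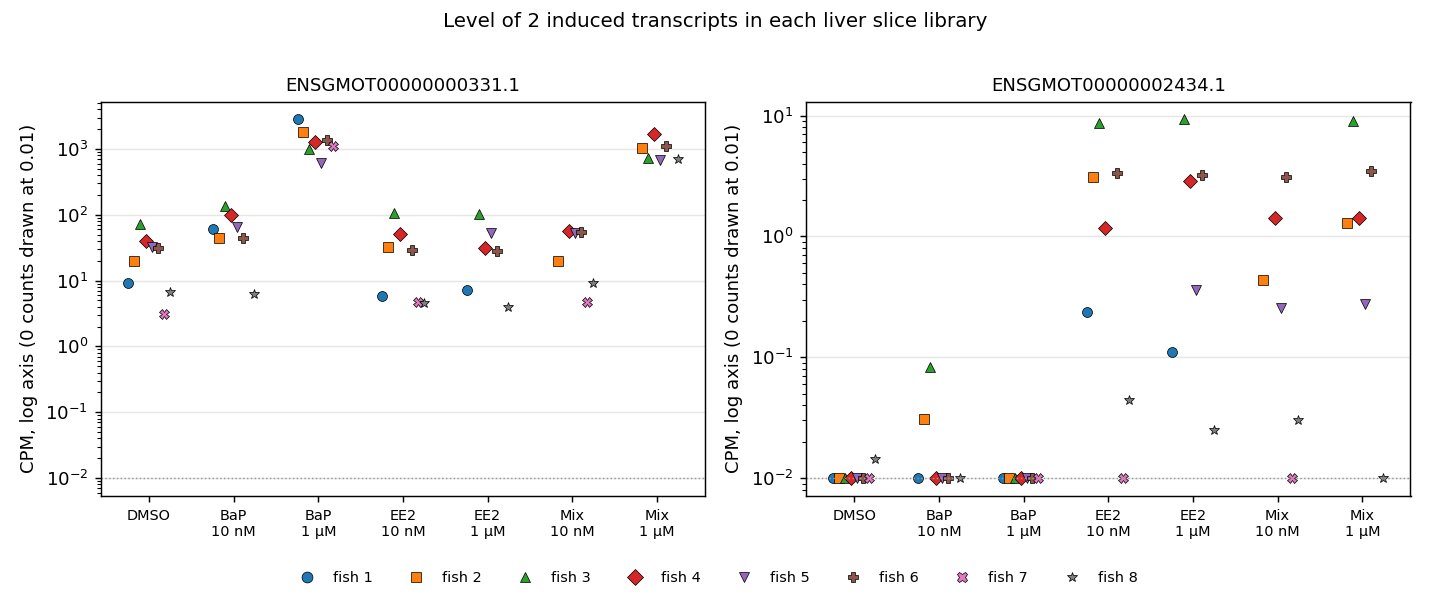
Level of ENSGMOT00000000331.1 (left) and ENSGMOT00000002434.1 (right) in each library, in CPM on a log axis, by treatment, with 1 symbol per fish and libraries with 0 counts drawn at 0.01. The left transcript reached 617 to 2810 CPM with BaP 1 µM and 674 to 1670 CPM with Mix 1 µM, against at most 73.1 CPM with DMSO, and the right one had 1 count in all DMSO libraries together.

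With EE2 10 nM, 50 transcripts rose against DMSO and 1 fell. The median rise was 3.08 on the log2 scale, and 26 of the called transcripts changed at least 8-fold. ENSGMOT00000002434.1, with a coding length of 321 bases, had 675 counts in the 7 EE2 libraries and 1 count in the 8 DMSO libraries. The ratio of the scaled counts was 800, with an exact 95% counting interval of 143 to 31700, and the edgeR adjusted p was 3.68e-09. With fish as a random effect in limma it did not pass, at a log2 fold change of 5.33 and an adjusted p of 0.33. Over the alternatives that tested it, the adjusted p lay between 3.27e-20 and 0.33. The stricter filter and the fit of only these groups filtered it out. Its level was 2.35 CPM ± 3.09 (SD, n = 7), it was higher in 6 of 7 fish, and in fish 7 and fish 8 it had 0 and 3 counts. Fish 3 held 352 of the 675 counts, and without it the level was 1.31 CPM ± 1.53 (SD, n = 6). The next transcript that rose by the naming rule had a log2 fold change of 5.82 ± 0.67 (SE) and was higher in 7 of 7 fish. The 1 transcript that fell was ENSGMOT00000008028.1, from 2.55 CPM ± 1.1 to 1.30 CPM ± 1.03 (SD, n = 7 fish with both slices). Its log2 fold change was -1.09 ± 0.24 (SE), lower in 7 of 7 fish, with an edgeR adjusted p of 0.0257 that lay between 0.00227 and 1 over the alternatives. Of the 41 members of the EE2 set, 31 rose and 41 had a log2 fold change above 0, with a median of 4.02. The mean change of the set per fish was 2.67 ± 0.81 (SD, n = 7), between 1.51 and 4.19, and it was above 0 in 7 of 7 fish, with an exact sign-flip p of 0.0156, the smallest possible with 7 fish, and an adjusted exact value of 0.0546. The count of calls was 11 without the fish block, 32 without fish 4 and 10 in the fit of only these groups. Without the 4 libraries it was 435, with 145 rises and 290 falls.

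With EE2 1 µM, 62 transcripts rose against DMSO and 0 fell. The median rise was 3.24 on the log2 scale, and 32 transcripts rose at least 8-fold. ENSGMOT00000002434.1 had 870 counts in 6 libraries, a ratio to DMSO of 1020 with an exact counting interval of 183 to 40400, and it was higher in 6 of 6 fish, in fish 8 with 2 counts against 1 count. Fish 3 held 542 of the counts, and without it the level went from 2.65 CPM ± 3.55 (SD, n = 6) to 1.32 CPM ± 1.59 (SD, n = 5). The transcript did not pass with fish as a random effect in limma (adjusted p of 0.167). In the EE2 set, 37 of 41 transcripts rose, and the set's mean change per fish was 3 ± 0.55 (SD, n = 6). ENSGMOT00000000331.1, which rose with BaP 1 µM, had a log2 fold change of 0.19 ± 0.47 (SE) with EE2 1 µM and did not pass the test. The count was 16 without the fish block and 26 in the fit of only these groups, and it was 89 without the 4 libraries.

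Both doses of EE2 called 46 transcripts in the same direction, where independent lists of these sizes would share 0.17. Both comparisons used the same DMSO slices. In 10 simulations without any treatment effect at most 0 transcripts were shared, a value that leaves out the effects and so does not measure what the shared slices add to the 46. The covariance of log2 fold changes across transcripts was 0.054, against 0.022 in the simulations, and their correlation was 0.75 against 0.43. With the DMSO slices split between the comparisons and without the fish block, each comparison called 1 transcript, the same 1, and the correlation was 0.10. The split gave odd-numbered fish to one comparison and even-numbered fish to the other, so differences between fish can lower the correlation. Without the block but with all DMSO slices, 11 and 16 were called. The split therefore cannot tell what the shared slices add. The same limit holds for the split DMSO slices given below for the mixtures. In EE2 1 µM against EE2 10 nM, 0 transcripts passed the edgeR test and 239 had an unadjusted p under 0.05, while DESeq2 and limma called 0. The fit of only these groups called 4. Without the 4 libraries 15 were called, and 0 once RLE factors or the length slope were used as well. The EE2 set was higher at 1 µM by a median of 0.33 on the log2 scale, with 34 of 41 members higher and a fry p adjusted over 14 readings of 0.0483. The mean difference per fish was 0.61 ± 0.19 (SD, n = 5), above 0 in 5 of 5 fish, with an exact sign-flip p of 0.0625, the smallest that 5 fish allow, and an adjusted exact value of 0.0875.

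With Mix 10 nM, 42 transcripts rose against DMSO and 0 fell, with a median rise of 4.40 on the log2 scale. Of these, 36 were also called with EE2 10 nM in the same direction, where independent lists would share 0.12 and the simulations shared 0. The covariance of fold changes was 0.045 against 0.022 in the simulations and the correlation was 0.62 against 0.44, and with split DMSO slices 1 transcript was shared and the correlation was -0.05. ENSGMOT00000002434.1 had 235 counts in 6 libraries, a ratio of 282 with an exact counting interval of 50.1 to 11200. It was higher in 5 of 6 fish, with 0 counts in fish 7, and it did not pass without the fish block (adjusted p of 0.103) or with fish as a random effect in limma (0.926). Fish 6 held 130 of the counts, and without it the level went from 0.869 CPM ± 1.2 (SD, n = 6) to 0.426 CPM ± 0.578 (SD, n = 5). The BaP set had a median log2 fold change of 0.31 and a fry p of 0.0909, and 0 of its members passed the edgeR test. Its mean change per fish was 0.38 ± 0.31 (SD, n = 6), above 0 in 6 of 6 fish, with an exact sign-flip p of 0.0312, the smallest possible with 6 fish, and an adjusted value of 0.0546. With EE2 10 nM alone the BaP set had a mean change per fish of 0.29 ± 0.44 (SD, n = 7), above 0 in 5 of 7 fish. In Mix 10 nM against BaP 10 nM the median of the BaP set was -0.47, with 1 of 6 members and 1 of 5 fish higher. The count was 7 without the fish block, 26 without fish 2, 26 without fish 4 and 2 in the fit of only these groups.

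With Mix 1 µM, 66 transcripts rose against DMSO and 7 fell. ENSGMOT00000000331.1 reached 991 CPM ± 384 (SD, n = 6), with a log2 fold change of 5.6 ± 0.53 (SE) and an edgeR adjusted p of 5.04e-09. ENSGMOT00000002434.1 had 706 counts, a ratio of 1110 with an exact counting interval of 199 to 44000. It was higher in 5 of 6 fish, and in fish 8 it had 0 counts against 1 count with DMSO. It did not pass with fish as a random effect in limma (adjusted p of 0.0878). Fish 3 held 395 of these counts, and without it the level went from 2.57 CPM ± 3.36 (SD, n = 6) to 1.29 CPM ± 1.37 (SD, n = 5). In the EE2 set, 33 of 41 transcripts rose, with a median log2 fold change of 4.38 and a mean change per fish of 2.88 ± 0.57 (SD, n = 6). The largest fall by the naming rule was that of ENSGMOT00000007691.1, from 36.1 CPM ± 42.6 to 25.6 CPM ± 30.9 (SD, n = 6 fish with both slices). Its mean over all DMSO slices was 69.8 CPM ± 74.7 (SD, n = 8), with 207 and 135 CPM in fish 1 and 7, which had no slice with Mix 1 µM. Without fish 2 its mean with Mix 1 µM was 14.1 CPM ± 14 (SD, n = 5), where the DMSO slices of the same fish had 5.8 to 35.3 CPM. Its log2 fold change was -1 ± 0.23 (SE), lower in 6 of 6 fish, with an edgeR adjusted p of 0.0274 that lay between 0.00338 and 1 over the alternatives. Against DMSO it was also below 0, without passing, with BaP 10 nM (-0.69), BaP 1 µM (-0.58), EE2 10 nM (-0.39), EE2 1 µM (-0.63) and Mix 10 nM (-0.51). Mix 1 µM differed from BaP 1 µM by -0.42 and from EE2 1 µM by -0.37, and neither passed, so the fall is not shown to be particular to the mixture. Of the calls, 51 were shared with EE2 1 µM and 7 with BaP 1 µM in the same direction, where independent lists would share 0.23 and 0.044 and the simulations shared 0. The covariances were 0.046 and 0.035, against 0.023 and 0.022 in the simulations. The correlations were 0.54 and 0.45, against 0.43 and 0.44 in the simulations, so that for BaP 1 µM it was about that of groups without an effect. With split DMSO slices 1 and 2 transcripts were shared, and the correlations were 0.46 and 0.05. The count of calls was 32 without the fish block, 43 without fish 3, 2 in the fit of only these groups and 132 with DESeq2.

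**Figure D2:**
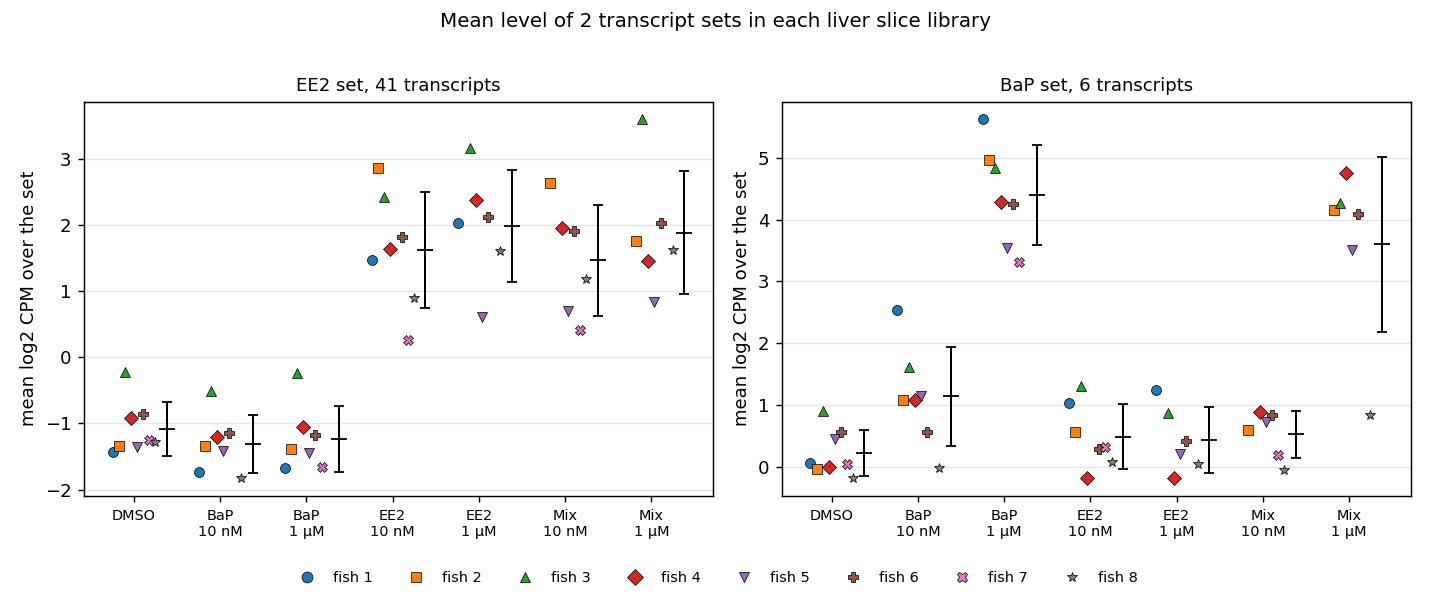
Mean log2 CPM of the 41 transcripts of the EE2 set (left) and the 6 transcripts of the BaP set (right) in each library, by treatment, with 1 symbol per fish and bars for the group mean ± SD. The EE2 set averaged -1.08 with DMSO, 1.62 with EE2 10 nM and 1.98 with EE2 1 µM, and the BaP set averaged 0.23 with DMSO and 4.40 with BaP 1 µM. Each set was picked in 2 of the groups drawn, Mix 10 nM and BaP 10 nM for the EE2 set and Mix 1 µM and EE2 1 µM for the BaP set.

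The effect of EE2 was also read in the presence of BaP. In Mix 10 nM against BaP 10 nM, 41 transcripts rose and 0 fell, and 31 of them were among the calls of EE2 10 nM against DMSO. In Mix 1 µM against BaP 1 µM, 48 rose and 6 fell, and 44 of these 54 were among the calls of EE2 1 µM against DMSO. The groups compared share no libraries, but both contrasts came from the fit of all libraries, so the lists are not independent. The fit of only Mix 1 µM and BaP 1 µM called 65, of which 33 were among the 54. Of the 62 transcripts called with EE2 1 µM against DMSO, 62 were higher in Mix 1 µM than in BaP 1 µM. Across those 62 transcripts, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.89 and a Spearman rho of 0.90. The EE2 set rose by a median of 4.31, with 36 of 41 members called. The counts were 6 and 12 without the fish block, 26 without fish 2 at 10 nM, and 31 without fish 3 at 1 µM. At 10 nM the fit of only these groups called 10, and at 1 µM DESeq2 called 83 and 89 were called without the 4 libraries. Falls at 1 µM numbered 15 with DESeq2 and 20 without the 4 libraries. They numbered 0 without the fish block, with fish as a random effect and in male fish.

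**Figure D3:**
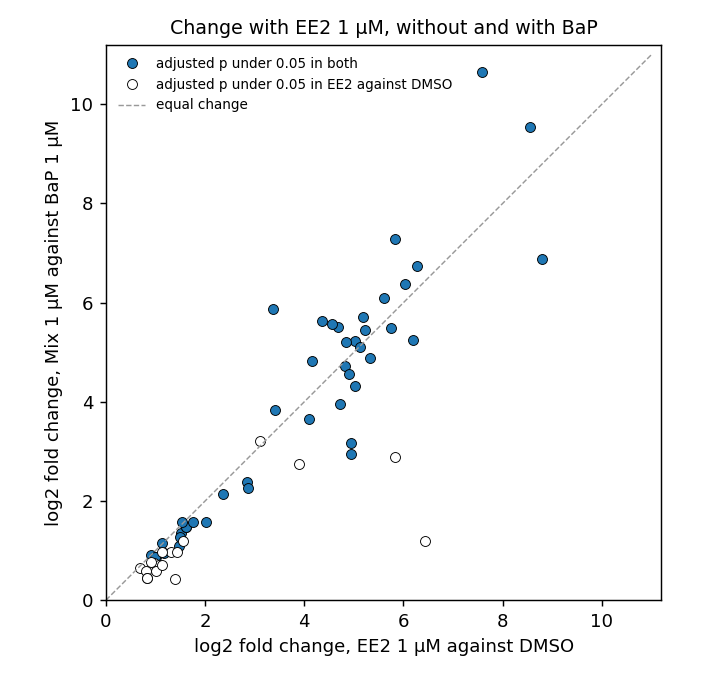
Log2 fold change of the 62 transcripts called in EE2 1 µM against DMSO (horizontal axis) and in Mix 1 µM against BaP 1 µM (vertical axis), with filled points for the 44 called in both and a dashed line of equal change. All 62 lie above 0 on both axes.

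The effect of BaP was read in the presence of EE2 in the same way. In Mix 1 µM against EE2 1 µM, 6 transcripts rose and 0 fell, and all 6 were among the 12 that rose with BaP 1 µM against DMSO. ENSGMOT00000000331.1 was higher by 5.40 ± 0.61 (SE) on the log2 scale, in 5 of 5 fish, with an edgeR adjusted p of 5.91e-07. In the fit of only these groups its log2 fold change was 4.99, but it did not pass (adjusted p of 0.757). The EE2 set had a median log2 fold change of -0.14 and a mean difference per fish of -0.07 ± 0.52 (SD, n = 5), with a fry p of 0.461. The count was 3 without fish 4, and 0 transcripts were called in the fit of only these groups. In Mix 10 nM against EE2 10 nM, 0 transcripts passed the edgeR test and 457 had an unadjusted p under 0.05, with 0 calls by DESeq2 and limma. Without the 4 libraries 5 were called there, and 0 once the length slope was used as well. The BaP set had a median log2 fold change of 0.19 there, with a fry p of 0.419. Between the mixtures, Mix 1 µM against Mix 10 nM gave 6 rises and 0 falls, the same 6 transcripts, and the fit of only these groups called 0. There ENSGMOT00000000331.1 had a log2 fold change of 4.98, against 5.03 in the reported fit, and an adjusted p of 0.0831.

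The interaction contrasts asked whether the change with the mixture differed from the sum of the changes with BaP and EE2. At 10 nM, 0 transcripts passed the edgeR test and 300 had an unadjusted p under 0.05, and at 1 µM 0 passed and 440 did. DESeq2 and limma called 0 in both. For ENSGMOT00000000331.1 the interaction was -0.82 ± 0.67 (SE) at 10 nM and -0.95 ± 0.71 (SE) at 1 µM on the log2 scale. For the EE2 set at 1 µM the median interaction was -0.11, with 18 of 41 members above 0, a fry p of 0.829 and a mean per fish of 0.05 ± 0.57 (SD, n = 4).

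Sex was compared in the same slices. Between the 3 female and 5 male DMSO slices, 0 of 16813 transcripts passed the edgeR test and 338 had an unadjusted p under 0.05, while DESeq2 called 12. With all libraries and fish as a random effect, limma called 9. The EE2 set averaged -0.79 ± 0.53 (SD, n = 3) log2 CPM in female and -1.26 ± 0.20 (SD, n = 5) in male DMSO slices, with a two-sided exact permutation p of 0.0536 and an adjusted value of 0.322 over 6 tests. The change of the EE2 set with EE2 10 nM was 2.50 ± 0.27 (SD, n = 3) in females and 2.79 ± 1.1 (SD, n = 4) in males, with an exact permutation p of 0.686. With EE2 1 µM it was 3.09 ± 0.26 (SD, n = 3) and 2.91 ± 0.82 (SD, n = 3), with an exact permutation p of 0.9, and with Mix 1 µM 3.20 ± 0.53 (SD, n = 3) and 2.56 ± 0.47 (SD, n = 3), with an exact permutation p of 0.3, where 3 fish against 3 allow 0.1 at the least. The change of the BaP set with BaP 1 µM was 3.80 ± 0.18 (SD, n = 2) in females and 4.24 ± 1.08 (SD, n = 5) in males, with an exact permutation p of 0.667. Interactions between sex and treatment called 0 transcripts in edgeR for BaP 1 µM, EE2 1 µM and Mix 1 µM, with 297, 235 and 2103 unadjusted p-values under 0.05. The 2103 exceed the share of 0.05 that chance alone would give. The female slices with Mix 1 µM include that of fish 8, 1 of the 4 libraries that stood apart. DESeq2 called 0, 1 and 0 there, and limma called 0 in each.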

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

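The 3 tests on the libraries that stood apart were chosen only after the result was seen, and the outlying values were found by a range rule fixed beforehand, under which about 1 in 20 groups exceeds the limit by chance. Of 81 groups checked, 8 had a value far from the others.

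The slice of fish 6 with BaP 10 nM had 17253 transcripts detected where the next lowest of its group had 18471, a TMM factor of 0.587 where the next was 0.992, and a standard deviation across transcripts, of log2 CPM minus the median of its fish, of 0.848 where the next was 0.276. The slice of fish 8 with Mix 1 µM had 15975 transcripts detected against 18017, a TMM factor of 0.572 against 0.962, and a standard deviation of 1.471 against 0.294. The slice of fish 7 with BaP 1 µM had a standard deviation of 1.414 against 0.370. Together with DMSO of fish 2, these were the 4 libraries with a TMM factor under 0.8.

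For these 4 libraries, lower sequencing depth would leave them with fewer mapped segments, but 2 of the 4, at 58.4 M and 62.1 M, had more than the median of 49.1 M of the other libraries. A trend with transcript length carried 21.4% to 34% of the variance of their deviations, so it does not account for most of it. A few transcripts taking most of the counts would lift the share of the 10 most abundant above that of the other libraries, but this held in 0 of the 4, whose shares of 17.3% to 20.4% lay within the 15.3% to 22.9% of the others, a bound that was restated after the values were seen. The deviations of the 4 correlated with each other at 0.70 to 0.89 and had length slopes of -0.786 to -0.374, a pattern shared across 4 fish and 4 treatments that is harder to explain by separate features of single slices. A difference in RNA quality common to them may remain, and it was not tested, since the labels say that RNA quality was assessed but give no value per slice; no biological explanation was tested.

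The mean change of the EE2 set with EE2 1 µM against DMSO was 1.96 on the log2 scale in fish 5, where the next lowest fish had 2.90.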

How the results depend on the processing

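The alternatives without the 4 libraries with low TMM factors, alone, with RLE factors or with the length slope, and the alternative without fish 7 and 8 were chosen only after the data were seen. Over 20 settings, the 4 printed transcripts gave 211 values for 11 results, of which 184 stayed past the threshold, 27 did not and 0 changed sign. The naming rule picked 10 transcripts with 25 results, and of these 17 did not pass with fish as a random effect, 10 in male fish and 8 without the block. The set medians gave 280 values, of which 262 moved by less than the spread between fish and 18 by more. For the 10 comparisons with calls, 144 of 200 counts stayed within 1.5 times the count reported, and for the 9 without calls 156 of 166 counts stayed at 0. The median log2 fold change of all transcripts lay between -0.045 and 0.062 over these settings, and between -0.025 and 0.039 in the reported fit. For the values that follow, the cause was not tested, except that the stricter filter tested 19 of the 41 EE2 set members and 4 of the 6 BaP set members, and that male fish alone or only the groups compared leave fewer slices.

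DESeq2 called 31 transcripts for BaP 1 µM, 132 for Mix 1 µM, 83 for Mix 1 µM against BaP 1 µM, 1 for the interaction of sex with EE2 1 µM and 12 between female and male DMSO slices, and the EE2 set median with EE2 1 µM was 4.07. The stricter filter gave 26 calls for EE2 10 nM, 33 for EE2 1 µM, 18 for Mix 10 nM, 45 for Mix 1 µM, 14 for Mix 10 nM against BaP 10 nM and 27 for Mix 1 µM against BaP 1 µM. Under it the EE2 set medians were 1.55 for EE2 10 nM, 2.03 for EE2 1 µM, 1.66 for Mix 1 µM and 1.59 for Mix 1 µM against BaP 1 µM, and the BaP set medians were 3.09 for BaP 1 µM and 2.45 between the BaP doses. Without the fish block the counts were 6 for BaP 1 µM, 11 for EE2 10 nM, 16 for EE2 1 µM, 7 for Mix 10 nM, 32 for Mix 1 µM, 6 for Mix 10 nM against BaP 10 nM and 12 for Mix 1 µM against BaP 1 µM. The EE2 set medians without the block were 0.15 for BaP 1 µM, where the sign changed without any member called, and 5.24 for Mix 1 µM.

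With fish as a random effect in limma the counts were 21 for EE2 10 nM, 39 for EE2 1 µM, 18 for Mix 10 nM, 35 for Mix 1 µM, 12 for Mix 10 nM against BaP 10 nM and 26 for Mix 1 µM against BaP 1 µM. Between female and male fish it called 9, in a model of all libraries and not of the DMSO slices alone. The EE2 set medians were 2.88 for EE2 10 nM and 3.37 for EE2 1 µM. With only the groups compared the counts were 3 for BaP 1 µM, 10 for EE2 10 nM, 26 for EE2 1 µM, 2 for Mix 10 nM, 2 for Mix 1 µM, 10 for Mix 10 nM against BaP 10 nM, 0 for Mix 1 µM against EE2 1 µM, 4 between the EE2 doses and 0 between the mixtures, and the EE2 set medians were 2.58 for EE2 10 nM, 4.04 for EE2 1 µM and 3.02 for Mix 1 µM. In male fish the counts were 6 for BaP 1 µM, 14 for EE2 10 nM, 11 for EE2 1 µM, 7 for Mix 10 nM, 11 for Mix 1 µM, 8 for Mix 10 nM against BaP 10 nM, 8 for Mix 1 µM against BaP 1 µM, and 2 each for Mix 1 µM against EE2 1 µM, between the BaP doses and between the mixtures, and the EE2 set medians were 3.28 for Mix 1 µM and 3.45 for Mix 1 µM against BaP 1 µM.

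Without the 4 libraries the counts were 1 for BaP 10 nM, 23 for BaP 1 µM, 435 for EE2 10 nM, 89 for Mix 1 µM against BaP 1 µM, 5 for Mix 10 nM against EE2 10 nM and 15 between the EE2 doses, and the EE2 set median with BaP 1 µM was -0.23. With RLE factors as well they were 1, 24, 389, 87 and 4 for the first 5 of these, and 0 between the EE2 doses. With the length slope they were 1 for BaP 10 nM, 78 for EE2 10 nM and 110 for Mix 1 µM, and 0 for Mix 10 nM against EE2 10 nM and between the EE2 doses.

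Leaving out each fish in turn gave 7 to 11 calls for BaP 1 µM, 32 to 51 for EE2 10 nM, 47 to 69 for EE2 1 µM, 26 to 40 for Mix 10 nM, 43 to 99 for Mix 1 µM, 26 to 39 for Mix 10 nM against BaP 10 nM, 31 to 57 for Mix 1 µM against BaP 1 µM, 3 to 6 for Mix 1 µM against EE2 1 µM, 4 to 7 between the BaP doses and 4 to 6 between the mixtures, and the EE2 set median with EE2 1 µM was 4.05 to 4.77. The lowest values came without fish 4 for BaP 1 µM (7) and EE2 10 nM (32), without fish 2 or fish 4 for Mix 10 nM (26), without fish 3 for Mix 1 µM (43) and Mix 1 µM against BaP 1 µM (31), without fish 2 for Mix 10 nM against BaP 10 nM (26), without fish 4 for Mix 1 µM against EE2 1 µM (3), and without fish 1 for the EE2 set median with EE2 1 µM (4.05). The falls of ENSGMOT00000008028.1 and ENSGMOT00000007691.1 passed the test in the reported fit but not without the block (adjusted p of 1 for each), with fish as a random effect, with only the groups compared or in male fish, and the second not without fish 7 and 8 together (0.0705). The first did not pass without fish 1, 2, 4, 5, 6 or 7 (adjusted p of 0.182, 0.0604, 0.355, 0.0629, 0.154 and 0.0630), and the second without fish 1, 2, 3, 6 or 8 (0.0612, 0.0522, 0.122, 0.161 and 0.0733).

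The alternatives for fixed gene lists were not run, because no identifier had a name, and the male alternative does not apply to comparisons of the sexes. A limit of 3 counts, 0.0448 to 0.0820 CPM, limits detection in a library.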

Other observations

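The tests of other splits for the 6 comparisons against DMSO and for Mix 10 nM against BaP 10 nM were chosen only after the result was seen, as were the fits without the 4 libraries with low TMM factors and the count of set members at the detection limit by fish. The splits for the falls with EE2 10 nM were run in the fit of all groups only after those in a fit of the slices compared had been seen, with 4 falls and at most 1 in its other splits.

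The response to EE2 was seen in each fish that had the slices, but single transcripts differed between fish. Of the 41 members of the EE2 set, the number at or under 3 counts in all EE2-exposed slices of a fish was 14 in fish 7, 11 in fish 8, 6 in fish 1, 1 in fish 5 and 0 in fish 2, 3, 4 and 6. Fish 1 and 7 had 2 such slices and the others 3 or 4, and with fewer slices a member is more easily at the limit in all of them. ENSGMOT00000002434.1 was highest in fish 3, at 8.60 CPM with EE2 10 nM and 9.28 CPM with EE2 1 µM.

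With BaP 1 µM alone, the mean of the EE2 set was lower than with DMSO in 7 of 7 fish, by a mean log2 difference of -0.18 ± 0.14 (SD, n = 7). The exact sign-flip p was 0.0156, the smallest possible, with an adjusted value of 0.0546. The fry p was 0.844, 17 of 41 members had a log2 fold change above 0, and 0 members passed the edgeR test.

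Transcripts at the limit in fish 7 and 8 may be lacking from their genomes or differ from the reference. No transcript was at the limit in all slices of both fish and above 1 CPM in the others, a count of 0. But all 28 pairs of fish gave 0, so the explanation cannot be told apart from a low response of these transcripts in both fish. The EE2 set as a whole changed in fish 8 by 2.90 with EE2 1 µM and 2.91 with Mix 1 µM, against means of 3 and 2.88. With EE2 10 nM it changed by 2.19 in fish 8 and 1.51 in fish 7, against a mean of 2.67.

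Without the 4 libraries, 290 transcripts fell with EE2 10 nM, and their median coding length was 3249 against 1137 for the tested transcripts. With each library's length slope as a covariate 3 of them still passed, their median log2 fold change went from -0.55 to -0.27 and the median SE from 0.14 to 0.12. The slope was lower in the EE2 slice in 5 of 6 fish, so a length trend between libraries may account for much of the pattern. But the slope was computed from the same levels, so a fall of long transcripts with EE2 would lower it too. The covariate cannot tell these explanations apart. With RLE factors 238 still passed, so the choice of TMM over RLE factors does not account for most of the falls. Both kinds give 1 factor per library, and an error common to both was not tested. In the same fit, 3 of 64 splits within fish gave as many falls, the real one included, a share under the twentieth part set beforehand, but 1 of these gave 808, so the real count does not lie beyond the spread of the splits, chance is not excluded, and a structure of the samples, not tested, is pointed to. An EE2 response stays open as untested. In Mix 10 nM against BaP 10 nM, other slices, the same transcripts had a median of -0.06, with 218 of the 290 lower and 0 called by edgeR. With EE2 1 µM, against the same DMSO slices, the median was -0.11, with 231 of the 290 lower and 1 called.

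Other splits of slices within fish were fitted with only the groups compared. For BaP 1 µM, 1 of 64 splits gave as many calls, the real one with 3 and the others at most 0. For EE2 10 nM the values were 1 of 64, 10 and 1. They were 1 of 32, 26 and 0 for EE2 1 µM, and 1 of 32, 4 and 0 for BaP 1 µM against BaP 10 nM. For Mix 10 nM they were 1 of 32, 2 and 0, and for Mix 1 µM 1 of 32, 2 and 1. Each share is under 0.05 and, read alone, argues against chance. These shares are the smallest such splits allow and were not adjusted over the comparisons, so chance is not excluded. The calls behind these shares are few for BaP 1 µM and both mixtures, 3 of the 12, 2 of the 42 and 2 of the 73 reported. By the number of calls the margin is smallest for Mix 1 µM. Where the real count was 0 the splits say nothing about chance, since any split gives as many. This holds for BaP 10 nM (64 of 64), the interactions of BaP and EE2 (40 of 40 at each dose), the interaction of sex with BaP 1 µM (21 of 21) and female against male DMSO slices (56 of 56, with 6 calls in another split).

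The splits were too few for a share under 0.05 in the remaining comparisons. The 16 splits gave a real value of 10 and a highest other value of 0 for Mix 10 nM against BaP 10 nM, 65 and 0 for Mix 1 µM against BaP 1 µM, 0 and 0 for Mix 10 nM against EE2 10 nM and for Mix 1 µM against EE2 1 µM, 4 and 2 between the EE2 doses, and 0 and 2 between the mixtures. The 10 splits for the interactions of sex with EE2 1 µM and with Mix 1 µM gave 0 and 0 each.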
